A study of Homo sapiens with 5 samples.

How the data were processed

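Total RNA of 5 cell lines was profiled by RNA sequencing, with 1 library per line. Per the labels' protocols, mRNA was enriched with oligo-dT and libraries were made with a directional kit, which keeps the strand. MKL-1, MKL-2, WaGa and MCC13 formed the Merkel cell carcinoma group (n = 4) and REH the pre-B-cell acute lymphoblastic leukemia (pre-B-ALL) group (n = 1), as named by the labels. Tissue samples mentioned in the description of the series were not analysed here. The 2 columns of values that matched no sample of the series, 1 in each table, were not used.

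Gene expression was used as TPM values computed by the authors for 57905 genes in a deposited table, and per the submitters' processing notes the tools were bcl2fastq 2.20, STAR 2.4.5b, StringTie 1.3.5 and SAMtools 0.1.19 with the builds hg19 and GRCh37. The notes give no role or order of these tools, and the gene annotation is not given in the sources used here. TPM values sum to the same total in every library and keep no depth, so the read depth behind a gene was unknown, and a change in a few abundant genes moves all others. An exact 0 in such a table can be a failed estimate, so such genes are described as listed at 0. Of the gene identifiers, 52338 were found in GENCODE 29, which was used for gene order, exon lengths and gene types, not for coordinates. There were 246 symbols shared by several identifiers.

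PAX5 exon use was taken from deposited signal values for 12 exons, which the authors had made by dividing read counts by 1 factor per library, as far as the deposited values themselves show. The counter and the scaling method are not given in the sources used here. In MKL-1, MKL-2, WaGa and REH every value was a whole multiple of 1 step, with a largest deviation of 4.6e-06 from a whole number, and dividing by the step gave the reads. All values of these 4 libraries came out whole. The MCC13 column held 1 value above 0, so its reads could not be recovered. If the counts shared a common divisor, the true numbers of reads would be larger than those given. Exon positions are those of the deposited table, 1-based, in the build of the submitters' notes.

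Genes were compared on the scale log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model with a variance trend, 2-sided, Benjamini-Hochberg adjusted p under 0.05). Differences on this scale understate the change of genes at low levels. Genes at 1 TPM or more in at least 1 of the lines compared were tested. The 4 Merkel cell carcinoma lines were compared with REH (22250 genes, 3 residual degrees of freedom), and each Merkel cell carcinoma line with the other 3 (20698 genes, 2 residual degrees of freedom). A lone line was assumed to vary as the lines of the other group do. Because each line had 1 library, line and library cannot be told apart, and p measures the spread between lines.

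Gene lists were tested with camera, part of limma, with its preset correlation of 0.01 and again with a correlation estimated from the residuals. Tests were adjusted over lists (and over lines for the comparisons between lines). With an estimated correlation camera also takes the residual degrees of freedom of the fit (3 or 2), so few lists can pass at any correlation. The 21 lists covered the PAX family, Merkel and neuroendocrine, early B lineage, PAX5-activated targets, pan-leukocyte, T and NK cell, myeloid, epithelial, keratinocyte, mesenchymal and adhesion, YAP and TAZ pathway, melanocyte, endothelial, MHC class I, MHC class II, interferon response, cell cycle, p53 target, neuronal, ribosomal protein, and MYC and tumour genes. Of 349 distinct symbols 347 were matched, and CD24 and PECAM1 were not. The lists, the tests, the rule for naming genes and the alternative settings were chosen before the data were examined. The rule named all PAX genes, the 12 genes with the largest passing difference in each direction between the Merkel cell carcinoma lines and REH whose REH value lay outside the range of the other 4, the genes with the largest gap between each line and the nearest of the other 3 (12 per direction for MCC13 and 6 for the others), and up to 4 members of each list with the largest difference. It passed over 23862 clone names, immunoglobulin segments and Y-linked genes. The names BCL2, IRF4, KRT14, MME, MTX2, PSMB10, ROBO1, TP63, TUBB3, YAP1 and ENO2 fall outside the rule and were chosen after their values were seen, most of them as the list members that passed. Some genes that the rule names are not reported here. They stay in every test, but are left off the list of values that stood apart.

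PAX5 exon shares were computed over all exons and again without E10, with exact (Clopper-Pearson) 95% binomial intervals from scipy 1.17.1 in Python 3.11.15, which cover counting error only. The design foresaw shares without a test if the exon values were not raw counts. The 2-sided Fisher's exact test on recovered reads (each exon against all others, each line against REH, Benjamini-Hochberg over 36 pairs, 33 without E10, or 30 without E10 and E1B), the total without E10 and E1B, and the ratio of E6/7 to E6 reads were added after the values had been seen. A read that spans a junction can count in more than 1 exon.

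The alternatives were pseudocounts of 0.1 and 5 TPM, no filter on low values, a mean of at least 5 TPM, quantile normalization, scaling to the median ratio over genes, no variance trend, each Merkel cell carcinoma line left out, the estimated correlation, exons with at least 20 reads, and exon reads divided by 2. Leaving out a line takes 1 residual degree of freedom from a limma fit. This by itself makes calls rarer, so a loss of calls there need not mean dependence on that line. Each procedure was tested on simulated data. For the 4 lines against REH, with 22250 genes and 50 changed genes per size, limma found 0, 4, 19 and 24 of 50 at log2 sizes of 2, 4, 6 and 8, with 2 of 49 calls false. With simulated values floored at 0 it found 0, 8, 23 and 27, with 31 of 89 calls false (34.8%). For MCC13 against the other 3 lines, with 20698 genes, it found 0, 0, 8 and 23 with 0 of 31 calls false. With the floor it found 0, 0, 9 and 20 with 6 of 35 false (17.1%). Camera found 5 of 5 shifted lists and called 0 of 15 others in both of these comparisons. The comparisons of MKL-1, MKL-2 and WaGa, each against a group that holds MCC13, were not simulated, so these rates need not hold for them. The simulated genes were independent of one another, so this does not show how often camera calls lists falsely where members vary together. In the data the estimated correlations reached 0.904 against REH (YAP and TAZ pathway) and 0.971 between lines (Merkel and neuroendocrine, in WaGa). Neither of these 2 lists passed there with the preset correlation. Among lists that passed, the estimates ran from -0.108 (myeloid) to 0.868 (Merkel and neuroendocrine) against REH. Between lines they ran from -0.193 (PAX family) to 0.934 (YAP and TAZ pathway), both in MKL-2. Fisher's exact test found a doubled exon in 50 of 50 simulated pairs and called 1 of 600 unchanged exons. Tables were handled with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.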

Results

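RNA sequencing was carried out on 5 human cell lines, with 1 library per line. The lines MKL-1, MKL-2, WaGa and MCC13 came from Merkel cell carcinoma, a neuroendocrine cancer of the skin. The remaining line, REH, came from a pre-B-cell acute lymphoblastic leukemia (pre-B-ALL). The series addressed PAX5, the transcription factor that commits lymphoid progenitors to the B lineage, in Merkel cell carcinoma. Transcript levels were given as TPM (transcript abundance scaled to the same total in every library) for 57905 genes, together with scaled read numbers for 12 PAX5 exons. Between 15949 genes (MCC13) and 16921 genes (MKL-2) reached 1 TPM in a line. The read depth of the TPM values was unknown. The PAX5 exon values corresponded to 45715 reads in MKL-1, 26222 in MKL-2, 13500 in WaGa and 73721 in REH. No line had a replicate library, so n counts lines and each SD is a spread between lines.

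PAX5 RNA was present in 3 of the 4 Merkel cell carcinoma lines. PAX5 (ENSG00000196092) stood at 91.9 TPM in MKL-1, 75.03 TPM in MKL-2 and 38.4 TPM in WaGa, against 186 TPM in REH and 0.023 TPM in MCC13. EBF1, which acts with PAX5 in early B-cell development, followed the same pattern, with 64.6, 52.7 and 55.5 TPM in MKL-1, MKL-2 and WaGa, 0.013 TPM in MCC13 and 120 TPM in REH. MCC13 lay below the other 3 Merkel cell carcinoma lines for both genes, by a log2(TPM + 1) difference of -6.00 ± 0.63 (SE) for PAX5 (limma, adjusted p = 0.0256) and -5.85 ± 0.29 for EBF1 (limma, adjusted p = 0.00855). Over all 4 Merkel cell carcinoma lines, PAX5 differed from REH by -3.02 ± 2.76 (SE, limma, adjusted p = 0.642), which was within the spread between lines. Without MCC13 the difference was -1.52 (limma, adjusted p = 0.211).

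Other PAX genes were also expressed. PAX6, a regulator of eye and neuroendocrine development, stood at 65.4, 109 and 78.1 TPM in MKL-1, MKL-2 and WaGa, and at 1.89 TPM in MCC13 and 0.279 TPM in REH. Its level in MCC13 was lower than in the other 3 lines (log2 difference -4.85 ± 0.39, limma, adjusted p = 0.0153). PAX2, a kidney and ear regulator, was higher in MCC13 at 44.0 TPM, against 0.099 to 1.54 TPM in the other 3 (log2 difference 4.95 ± 0.69, limma, adjusted p = 0.046). PAX9 reached 12.2 TPM in MKL-2 and at most 1.03 TPM elsewhere. PAX8 stood at 3.18 TPM in MKL-1 and 3.30 TPM in MKL-2, and at most 0.016 TPM in the remaining lines. PAX1, PAX3, PAX4 and PAX7 stayed below 1 TPM in all 5 lines.

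**Figure D1:**
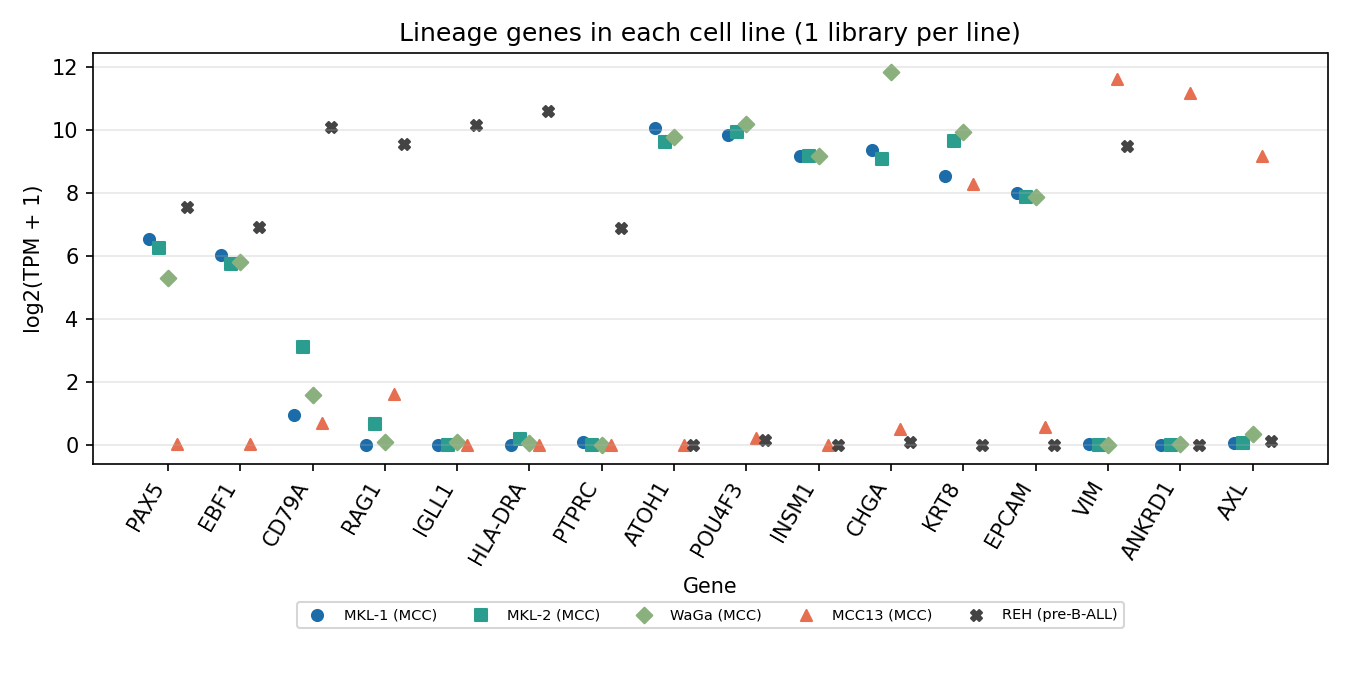
Level of 16 genes (x axis) in each cell line as log2(TPM + 1) (y axis), 1 point per library, for 4 Merkel cell carcinoma (MCC) lines and the pre-B-ALL line REH. PAX5 and EBF1 lie at 38.4 TPM or more in MKL-1, MKL-2, WaGa and REH, whereas IGLL1 stands at 1147 TPM in REH and at most 0.060 TPM in the 4 Merkel cell carcinoma lines.

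The Merkel cell carcinoma lines were compared with REH to ask how far the group shared its B-lineage programme. MCC13, with PAX5 at 0.023 TPM, was included, so the counts below do not describe the PAX5-expressing lines alone. Most early B-cell genes abundant in REH were near 0 in the Merkel cell carcinoma lines. Of 20 tested genes of the early B lineage list, 14 were lower in the Merkel cell carcinoma lines and none was higher (18 lower when adjusted over the list alone), with a median log2 difference of -7.19. IGLL1, a surrogate light chain gene, stood at 1147 TPM in REH and at most 0.060 TPM elsewhere. RAG1, which cuts antigen receptor loci, stood at 745 TPM in REH and at most 2.04 TPM elsewhere. CD79A, a B-cell receptor signalling chain, stood at 1091 TPM in REH and between 0.632 and 7.67 TPM elsewhere. DNTT, the template-independent polymerase of V(D)J joining, did not pass (1814 TPM in REH and 22.4 TPM in MKL-1, limma, adjusted p = 0.0786). Nor did BLK, a B-cell kinase, at 34.3 TPM in MKL-2 and 85.7 TPM in REH (limma, adjusted p = 0.364). The list was lower by camera (adjusted p = 9.89e-19) and also by adjusted p = 0.0445 with an estimated correlation.

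Of 16 tested genes on a list of textbook PAX5-activated targets, 10 of whose entries were also early B genes, 8 were lower in the Merkel cell carcinoma lines and none was higher (10 lower when adjusted over the list alone). RAG2 stood at 159 TPM and BLNK, an adaptor of the B-cell receptor, at 130 TPM in REH, and both were below 0.14 TPM in every Merkel cell carcinoma line. Among pan-leukocyte genes, 8 of 20 were lower (12 when adjusted over the list alone), including SPN and HCLS1 at 202 and 249 TPM in REH and at most 0.532 TPM elsewhere. In the MHC class II list, which covers antigen presentation to CD4 T cells, 7 of 10 genes were lower (10 when adjusted over the list alone). HLA-DRA stood at 1547 TPM in REH and at most 0.139 TPM elsewhere, and CD74, the invariant chain, at 2444 TPM and at most 12.5 TPM. Each of these 3 lists was lower by camera (adjusted p = 1.80e-08, 1.21e-11 and 1.40e-11). With an estimated correlation none passed, although the estimates themselves were low (0.019, 0.045 and 4.1e-05). That setting also took the 3 residual degrees of freedom of the fit. Of 6 tested myeloid genes, 4 were lower, among them AIF1 (524 TPM in REH and listed at 0 elsewhere) and MPO (156 TPM in REH), with camera adjusted p = 0.000717 and adjusted p = 0.134 with an estimated correlation.

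Among the genes higher in the Merkel cell carcinoma lines with the largest differences, the keratins KRT8 and KRT18, of simple epithelium, stood at 614 ± 322 TPM and 185 ± 69.8 TPM (SD, n = 4) and were listed at 0 in REH. UCHL1, a neuronal ubiquitin hydrolase, stood at 624 ± 239 TPM, TAGLN2, an actin-binding protein, at 1108 ± 1000 TPM, and CDH2, N-cadherin, at 179 ± 46.3 TPM, each listed at 0 in REH. KIF1A, a motor of axonal transport, was listed at 0 in REH as well and stood at 455 ± 319 TPM. NGFRAP1, SCD, CBS, DPYSL3 and PYCR1 were each below 0.2 TPM in REH, with CBS, a transsulfuration enzyme, the least variable at 233 ± 25.2 TPM (log2 difference 7.82 ± 0.27 (SE), limma, adjusted p = 0.00572). Across these genes, log2 differences ran from 7.44 to 9.77 and limma adjusted p from 0.00572 to 0.0499. The remaining genes of the opposite group, higher in REH, were HLA-DRB1, APBB1IP, S1PR4, RCSD1 and VPREB3, at 379 to 891 TPM in REH and at most 1.05 TPM elsewhere. HLA-DRB1 has near-identical copies, so its level is uncertain.

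Neuronal genes were higher in the Merkel cell carcinoma lines for 4 of 22 members (also 4 when adjusted over the list alone), namely UCHL1, INA, TUBB3 and ROBO1. INA, a neuronal intermediate filament, stood at 66.7 to 99.9 TPM and was listed at 0 in REH. The list was higher by camera (adjusted p = 1.16e-06) but not with an estimated correlation (adjusted p = 0.51). Of 17 tested epithelial genes, 2 (KRT8 and KRT18) were higher (camera adjusted p = 0.00149, and adjusted p = 0.51 with an estimated correlation). On the Merkel and neuroendocrine list, which shares 2 genes with the neuronal list, none of 22 genes passed, although all 22 differences were positive (median 5.01). ATOH1, the Merkel cell master regulator, stood at 789 to 1067 TPM in MKL-1, MKL-2 and WaGa and was listed at 0 in both MCC13 and REH. CHGA, chromogranin A, stood at 540 to 3693 TPM in the same 3 lines, 0.415 TPM in MCC13 and 0.070 TPM in REH. The list was higher by camera (adjusted p = 0.000827) and not with an estimated correlation (adjusted p = 0.692).

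For the MHC class I pathway no gene of 15 passed, and 14 of the differences were negative. HLA-B stood at 0.064, 15.1, 322 and 700 TPM in MKL-1, MKL-2, WaGa and MCC13 against 2451 TPM in REH, and PSMB9, an immunoproteasome subunit, was listed at 0 in MKL-1 and WaGa against 378 TPM in REH. The list was lower by camera (adjusted p = 0.00571, and adjusted p = 0.685 with an estimated correlation). Of 20 interferon response genes, 2 were lower, OAS2 and MX2 (camera adjusted p = 0.00156, and adjusted p = 0.51 with an estimated correlation). Of 28 ribosomal protein genes, 2 were lower, RPS23 and RPS3 (camera adjusted p = 0.0412, adjusted p = 0.692 with an estimated correlation, and adjusted p = 0.271 after quantile normalization). Lists for T and NK cells, keratinocytes, mesenchymal and adhesion genes, YAP and TAZ pathway genes, melanocytes, endothelium, the cell cycle, p53 targets, PAX family and MYC and tumour genes did not pass by camera (adjusted p from 0.113 to 0.698). Of the MYC and tumour genes, 1 was higher when adjusted over the list alone. Single members passed in 3 of these lists: NKG7 (T and NK cell) and TP63 (keratinocyte) were lower, and TEAD1 (YAP and TAZ) was higher.

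In total, 1166 of 22250 tested genes differed between the Merkel cell carcinoma lines and REH, 243 higher and 923 lower in the former (limma on log2(TPM + 1), adjusted p under 0.05). The median difference over all tested genes was 0.18, and 0.03 after quantile normalization. Mitochondrially encoded genes took 0.783% of the TPM total in REH and 3.52% to 7.84% in the other lines. MTX2, a mitochondrial import gene, and 20 others at 50 TPM or more in each Merkel cell carcinoma line were listed at exactly 0 in REH, which can be a failed estimate. KRT8, KRT18, UCHL1, TAGLN2, CDH2, KIF1A and INA, named above as higher in the Merkel cell carcinoma lines, were among them, so this limit applies to their differences. The comparison rested on 1 pre-B-ALL library, and an exact permutation test of 4 lines against 1 cannot give p below 0.2. No gene passed when MKL-1, MKL-2 or WaGa was left out (3194, 3432 and 3288 genes at unadjusted p under 0.05), 2828 passed without MCC13 (1038 higher and 1790 lower, 1149 of them shared with the 1166), and 288 passed (160 higher and 128 lower) among genes averaging 5 TPM or more. On data simulated with values floored at 0, 31 of 89 calls of this test were false (34.8%), against 2 of 49 (4.08%) without the floor.

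**Figure D2:**
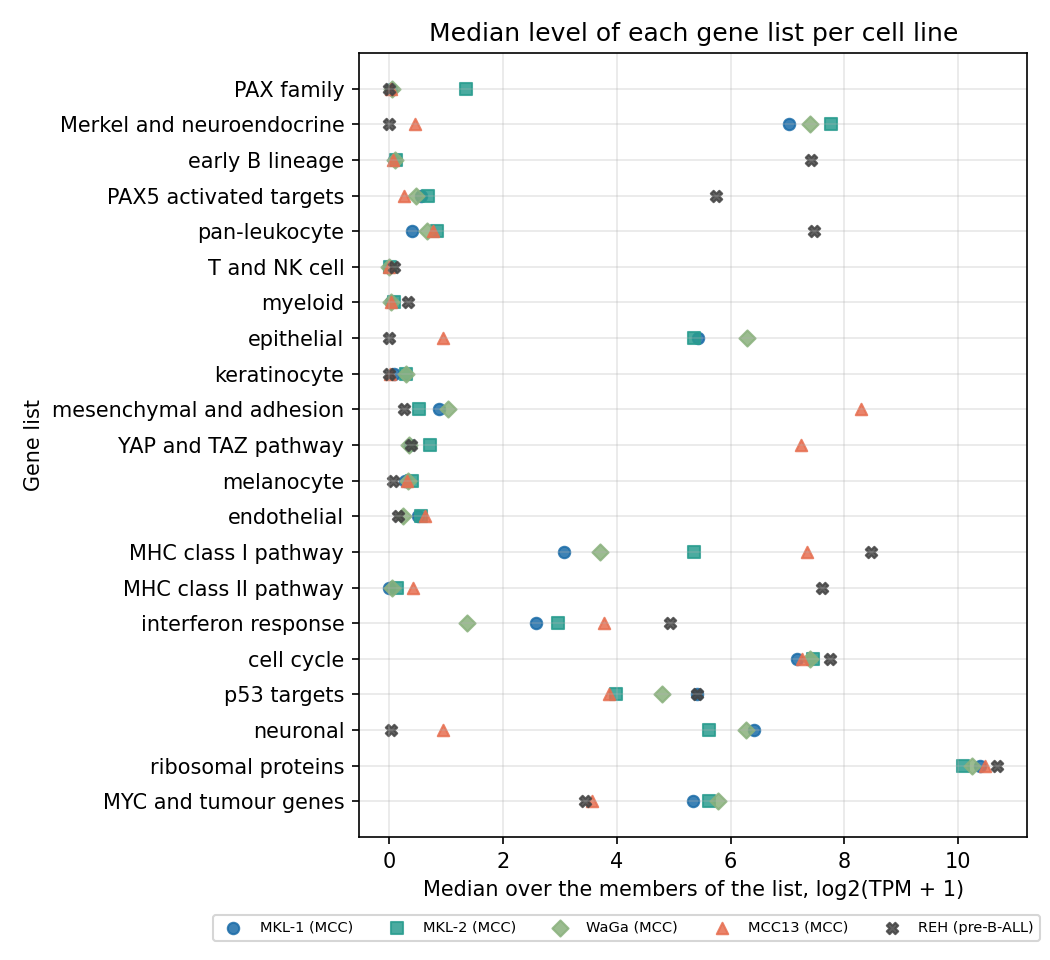
Median log2(TPM + 1) over all matched members of each gene list (x axis, 1 point per cell line) for the 21 lists (y axis). The early B lineage median is 7.41 in REH and at most 0.11 in the Merkel cell carcinoma (MCC) lines, and the mesenchymal and adhesion median is 8.30 in MCC13 and at most 1.03 in the other lines.

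Each Merkel cell carcinoma line was then compared with the other 3 in the same way. In MCC13 most Merkel and neuroendocrine genes were lower and most mesenchymal genes were higher. Of 22 tested Merkel and neuroendocrine genes, 14 were lower in MCC13 and none was higher (18 lower when adjusted over the list alone). ATOH1 and INSM1, a neuroendocrine zinc finger factor, stood at 909 ± 143 and 575 ± 5.27 TPM (SD, n = 3) in the other 3 lines and were listed at 0 in MCC13. POU4F3, a sensory cell factor, stood at 1018 ± 135 TPM against 0.165 TPM, and ISL1 at 331 ± 87.5 TPM against a listed 0. The log2 differences of these 4 genes were -9.82 ± 0.26, -9.17 ± 0.17, -9.76 ± 0.24 and -8.34 ± 0.37 (SE, limma, adjusted p = 0.00855 for each). CHGA was lower by -9.60 ± 1.38 (limma, adjusted p = 0.0491). Of 22 neuronal genes 9 were lower (12 when adjusted over the list alone), including the neurofilament genes NEFL and NEFM, below 0.04 TPM in MCC13 and at 188 to 468 TPM in the other 3. Of 17 epithelial genes 8 were lower and 1 was higher (10 and 1 when adjusted over the list alone). EPCAM and the splicing regulator ESRP1 stood at 0.484 TPM and a listed 0, against 232 to 253 and 139 to 214 TPM. KRT8 and KRT18 did not pass (313 and 229 TPM in MCC13, limma, adjusted p = 0.401 and 0.659).

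Of 31 tested mesenchymal and adhesion genes, 17 were higher in MCC13 and none was lower (24 higher when adjusted over the list alone), with a median log2 difference of 6.30. VIM, the mesenchymal intermediate filament vimentin, stood at 3125 TPM in MCC13 and at most 0.029 TPM in the other 3 (log2 difference 11.60 ± 0.36 (SE), limma, adjusted p = 0.00855). LGALS1 stood at 3257 TPM against at most 4.02 TPM, and FN1, fibronectin, at 1869 TPM against at most 7.04 TPM. Of 12 genes on the YAP and TAZ pathway list, which shares AXL with the mesenchymal list, 9 were higher (10 when adjusted over the list alone). YAP1 itself stood at 100 TPM against at most 0.010 TPM, WWTR1, which encodes TAZ, at 408 TPM against at most 1.84 TPM, and ANKRD1, a transcript induced by both, at 2320 TPM against at most 0.021 TPM. Other genes with large gaps above the remaining lines were CCND1 (cyclin D1, 1484 TPM), TM4SF1 (1136 TPM), AKAP12 (1026 TPM), IGFBP7 (949 TPM), MMP1 (829 TPM), MSN (798 TPM), COL4A1 (793 TPM), GJA1 (788 TPM) and COL4A2 (766 TPM), each at most 0.300 TPM in the other 3. Those below were CCER2, PCP4, SCNN1A, GNG8, KCNH6, HEPACAM2 and the mitochondrial pseudogene MTATP6P1, at most 0.296 TPM in MCC13 and 274.9 to 4136 TPM in the other 3. Reads of MTATP6P1 can be shared with the mitochondrial genome, so its level is uncertain.

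On the MYC and tumour genes list, 4 of 14 genes were lower in MCC13 (1 higher and 4 lower when adjusted over the list alone), although the list did not pass by camera (adjusted p = 0.124). RB1, the retinoblastoma suppressor, stood at 2.56 TPM in MCC13 and 57.3 to 82.9 TPM in the other 3 (log2 difference -4.30 ± 0.32 (SE), limma, adjusted p = 0.0136). MYCL, a MYC paralog, stood at 0.148 TPM against 87.0 to 127 TPM, KIT at 1.84 TPM against 31.5 to 58.6 TPM, and BCL2, an inhibitor of apoptosis, at 6.65 TPM against 52.8 to 61.7 TPM. Of 13 tested pan-leukocyte genes 3 were higher in MCC13, namely ARHGDIB (202 TPM), RAC2 (168 TPM) and ITGA4 (21.5 TPM). Of 25 cell cycle genes 3 were lower, MCM6, E2F2 and CCNE2. In the MHC class I pathway 1 gene of 15, PSMB10, was higher at 60.6 TPM against 7.44 to 10.0 TPM, and no gene passed when adjusted over the list alone. Members that were higher in the other lists were IL7R and MME (early B lineage, 15.4 TPM for IL7R), IRF4 and NEDD9 (PAX5 targets), CD8A (1.05 TPM), CD68, KRT14 and DSC3 (61.7 TPM), ENG, HLA-DPA1, HLA-DPB1 and HLA-DMB, IFI44 and DDX58, and TNFRSF10B.

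The MCC13 lists that passed by camera were Merkel and neuroendocrine (lower, adjusted p = 1.53e-11), neuronal (lower, 1.03e-05), epithelial (lower, 0.00334), mesenchymal and adhesion (higher, 1.02e-15), YAP and TAZ pathway (higher, 5.22e-09), MHC class I pathway (higher, 0.00472) and pan-leukocyte (higher, 0.026). None of them passed with an estimated correlation. The estimates lay between -0.052 and 0.050 for all of these lists except MHC class I (0.401). That setting also took the 2 residual degrees of freedom of the fit. Failing to pass there does not by itself show that members of a list varied together. The keratinocyte, MHC class II, interferon response, early B lineage, PAX5 target, PAX family, myeloid, melanocyte, endothelial, cell cycle, p53 target, ribosomal and MYC and tumour lists did not pass (camera adjusted p from 0.0509 to 0.943). Their early B lineage median and mean were negative (-0.83 and -0.79) while camera ranked the list upward, and the melanocyte median was -0.42 with a mean of 0.36. The T and NK cell list had 2 tested genes and was not tested as a list.

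In total, 1852 of 20698 genes differed between MCC13 and the other 3 lines, 1340 higher and 512 lower (limma, adjusted p under 0.05), with a median difference over all genes of -0.30 (-0.13 after quantile normalization). MCC13 was a single library, and an exact permutation test of 1 line against 3 cannot give p below 0.25. When MKL-1, MKL-2 or WaGa was left out, no gene passed in limma, with 4414, 4978 and 4579 genes at unadjusted p under 0.05. Among genes averaging 5 TPM or more, 543 were higher and 624 lower, so the excess of higher genes did not hold there.

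MKL-1, MKL-2 and WaGa were close to one another, with Pearson correlations across genes of 0.908 to 0.929, against 0.734 to 0.747 with MCC13 and 0.702 to 0.709 with REH. MCC13 and REH correlated at 0.738, within the range of MCC13 with those 3 lines. Genes are not independent replicates. No gene passed in limma for MKL-1, MKL-2 or WaGa against the other 3 lines, where 296, 638 and 467 genes had an unadjusted p under 0.05, so values are given without a call. MKL-1 had the cyclin-dependent kinase inhibitor gene CDKN2A listed at 0 and MTAP, its neighbour, at 0.780 TPM, against 143 to 246 and 32.8 to 56.8 TPM in the other 3 lines. TES, SOX12, TMBIM1 and HLA-B were also lowest there among the 4 Merkel cell carcinoma lines, at 0.015, 0.83, 2.73 and 0.064 TPM. Among the same 4 lines, MKL-1 had the highest levels of HAND2, a sympathoadrenal factor (124 TPM), HAND2-AS1 (25.7 TPM), SLC38A5 (168 TPM, against 274 TPM in REH), MT-TK (1282 TPM), FGF7 (22.8 TPM) and MYO3A (16.8 TPM). MKL-2 had the highest levels of SOX2-OT (542 TPM), RORB (95.3 TPM), NELL1 (292 TPM), SLC12A7 (891 TPM), SLC6A19 (38.7 TPM) and STC1 (248 TPM). HIST1H2BK, BLOC1S5-TXNDC5 and NSMAF were listed at 0 in MKL-2, and ZNF22, SNHG14 and SELM stood at 0.033, 0.074 and 1.87 TPM. WaGa had the highest levels of LGALS7 (2578 TPM), GPX2 (278 TPM), CTAG1B and CTAG1A (47.4 and 47.3 TPM), KLRG2 (89.1 TPM) and S100A14 (211 TPM). PEG10, CTSC and BIVM-ERCC5 were listed at 0 in WaGa, and SGCE, BASP1 and DSG2 stood at 0.090, 0.150 and 0.159 TPM. Values of CTAG1A, CTAG1B and LGALS7, which have near-identical copies, of the histone gene HIST1H2BK and of the readthrough genes BLOC1S5-TXNDC5 and BIVM-ERCC5, which overlap others, are uncertain.

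By camera, 7 lists passed in MKL-1 and 7 in MKL-2, and 3 passed in WaGa, none with an estimated correlation (adjusted p from 0.764 to 0.868). MKL-1 was higher for the Merkel and neuroendocrine (adjusted p = 0.0254) and neuronal (0.00795) lists and lower for the MHC class I (9.85e-07), mesenchymal (0.000422), YAP and TAZ (0.00166), keratinocyte (0.023) and pan-leukocyte (0.0485) lists. MKL-2 was higher for the Merkel and neuroendocrine (0.00182), epithelial (0.016), PAX5 target (0.042) and PAX family (0.0452) lists and lower for the mesenchymal (2.61e-05), ribosomal (0.00977) and YAP and TAZ (0.042) lists. WaGa was lower for the interferon response (3.68e-05), MHC class I (0.00554) and mesenchymal (0.0338) lists. Without MCC13 the direction turned for the Merkel and neuroendocrine list in MKL-1 (adjusted p = 0.172), the YAP and TAZ list in MKL-2 (0.463) and the mesenchymal list in WaGa (0.176), none of which then passed. Without MCC13 there were 6 calls. MKL-1 stayed lower for MHC class I (0.00534), WaGa stayed lower for the interferon response (0.00196), and MKL-2 was higher for MHC class I (0.000325), interferon response (0.0102) and the PAX family (0.0157) and lower for p53 targets (0.0406). TAP1 and PSMB8, of peptide transport and processing, stood at 0.333 and 2.17 TPM in MKL-1, 0.399 and 1.64 TPM in WaGa, and 40.2 and 104 TPM in MKL-2. HLA-B and HLA-C ran otherwise, at 15.1 and 15.5 TPM in MKL-2 against 322 and 243 TPM in WaGa.

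The use of PAX5 exons was compared between each Merkel cell carcinoma line and REH. In the build given by the submitters (GRCh37), the exons lay on the minus strand of chromosome 9, from E1A (37033983 to 37034028) to E10 (36833272 to 36840633). MCC13 had signal in E10 alone (8.08 scaled reads), so its exon use could not be described. In the other lines E10, of 7362 bp, took most reads, with 72.5% in MKL-1, 71.3% in MKL-2 and 70.1% in WaGa against 62.0% in REH. Over all exons, the profile of each Merkel cell carcinoma line differed from that of REH by 13.5 ± 1.11 percentage points (SD, n = 3 lines), and by 24.0 ± 2.22 with E10 left out. These distances are sums over shares and were not tested. Shares are given over the 12578, 7525, 4031 and 28015 reads outside E10 in MKL-1, MKL-2, WaGa and REH, with exact 95% binomial intervals that cover counting error only.

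Exon E6/7 (chromosome 9, 36930885 to 36930941, 57 bp), which lies between E6 and E7 and has the length of an exon in 2 GENCODE 29 transcripts of PAX5, held more reads in the Merkel cell carcinoma lines than in REH. It had 54 reads in MKL-1 (0.429%, interval 0.323 to 0.56), 16 in MKL-2 (0.213%, 0.122 to 0.345) and 25 in WaGa (0.62%, 0.402 to 0.914), against 5 reads in REH (0.0178%, 0.0058 to 0.0416). Per 100 reads in E6 there were 3.75, 1.91 and 5.52 E6/7 reads in the Merkel cell carcinoma lines and 0.158 in REH (2-sided Fisher's exact test, adjusted p = 2.58e-21, 1.05e-07 and 5.59e-18). Between Merkel cell carcinoma lines, MKL-2 had the lowest ratio (Fisher's exact test, adjusted p = 0.00401 against WaGa and 0.0248 against MKL-1), and MKL-1 against WaGa did not pass (adjusted p = 0.139). With 1 library per line, these p values cover counting error only, and a difference between lines cannot be separated from one between libraries.

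E1B (37026530 to 37027676, 1147 bp), whose length matches an exon in 0 GENCODE 29 transcripts of PAX5, held the smaller share in the Merkel cell carcinoma lines, with 20.2% in MKL-1 (interval 19.5 to 20.9), 24.5% in MKL-2 (23.5 to 25.5) and 24.2% in WaGa (22.8 to 25.5) against 46.1% in REH (45.5 to 46.7). Shares sum to a fixed total, so a smaller E1B share by itself raises the shares of all other exons. E3 (37014994 to 37015191) held 14.0%, 13.7% and 12.1% against 5.90%, and E4 (37006470 to 37006534) 9.63%, 9.83% and 8.48% against 5.06%. E7 (36923352 to 36923481), E8 (36882001 to 36882102) and E9 (36846840 to 36846926) were likewise higher, with E7 at 9.15%, 8.16% and 9.53% against 4.42% and log2 ratios for the 3 exons between 0.51 and 1.11. The direction of E2 (37020633 to 37020798) depended on the total, with log2 ratios of 0.24 to 0.34 outside E10 and of -0.14, -0.07 and -0.11 with E10 included, where it was lower in MKL-1 (Fisher's exact test, adjusted p = 0.00916). With E10 in the total E8 did not pass in MKL-2 (Fisher's exact test, adjusted p = 0.199). The shares of E5 (37002645 to 37002773) and E6 (36966546 to 36966721) lay between 10.8% and 11.5% in the Merkel cell carcinoma lines and at 11.8% and 11.3% in REH, and did not pass in any line (Fisher's exact test, adjusted p from 0.0679 to 0.936). With E10 in the total, both were lower in the 3 lines, at 3.08% to 3.36% against 4.48% and 4.29%. E1A held 1.07%, 0.571% and 0.744% against 0.435%, and passed in MKL-1 and WaGa but not in MKL-2 (Fisher's exact test, adjusted p = 0.144). In WaGa it did not pass with E10 in the total (Fisher's exact test, adjusted p = 0.163). By Fisher's exact test, 26 of 33 pairs of exon and line differed from REH outside E10, and 31 of 36 with E10 included. With both E10 and E1B left out of the total, 27 of 30 pairs differed. E3, E4, E7, E9 and E6/7 stayed higher in the 3 lines, with log2 ratios of 0.54 to 0.73 for E3, whereas E2 (-0.26 to -0.15), E5 (-0.64 to -0.57) and E6 (-0.55 to -0.50) were lower in all 3. E8 in MKL-2 and E1A in MKL-2 and WaGa did not pass (Fisher's exact test, adjusted p = 0.774, 0.793 and 0.351). Each test compared 2 libraries, not tumour types, covers counting error only, and was added after the values had been seen.

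**Figure D3:**
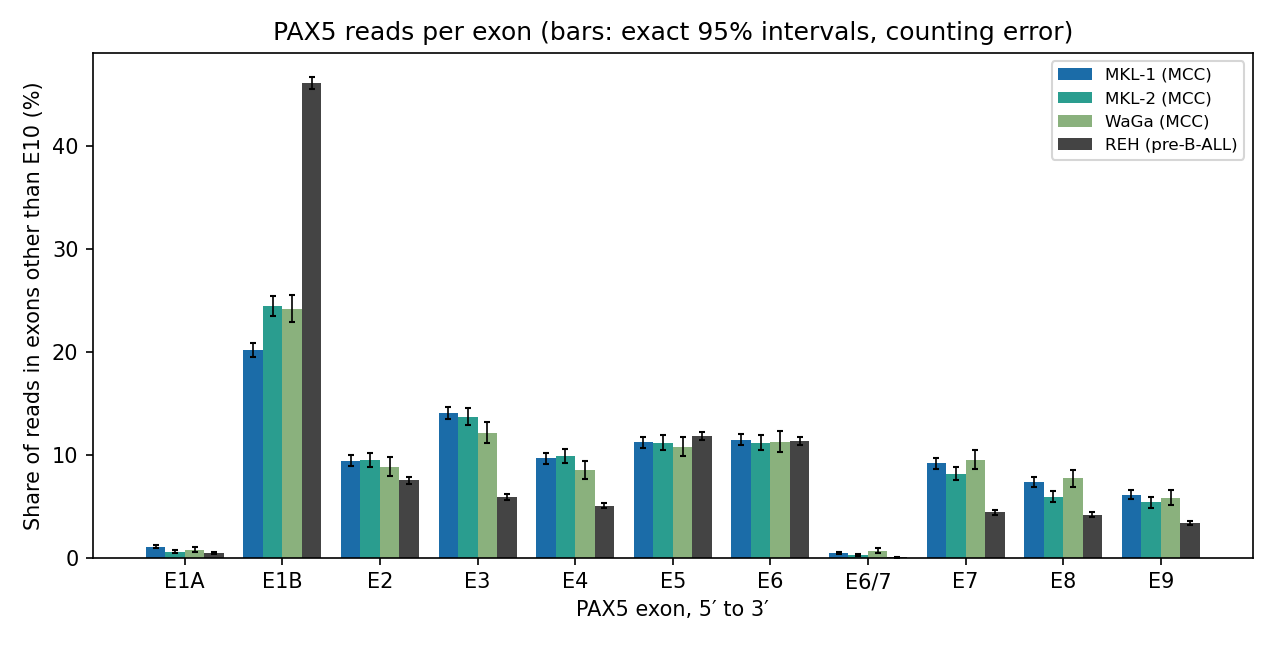
Share of PAX5 reads outside E10 that fell in each exon (y axis, percent) along the transcript from 5′ to 3′ (x axis), for 3 Merkel cell carcinoma (MCC) lines and REH. Bars are single libraries with exact 95% binomial intervals. E1B holds 46.1% in REH and 20.2% to 24.5% in the other lines, and E3 holds 5.90% in REH and 12.1% to 14.0% in the others.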

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

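All tests of explanations in this part were chosen after the results had been seen. Within the 4 Merkel cell carcinoma lines, a value stood apart where its gap to the nearest other line exceeded 0.83 of the whole range (Dixon's 95% critical value for 4 samples). For normally distributed values chance gives this in about 1 in 20 groups. Many genes named below were chosen for a large gap in 1 line, so that rate does not hold for them. Nor need it hold for genes at very low levels, whose values cannot fall below a floor. Over all 20698 genes, 1971 stood apart in MCC13, 355 in MKL-2, 319 in WaGa and 246 in MKL-1. Whether the counts for MKL-2, WaGa and MKL-1 exceed what chance gives was not tested. Standing apart there describes a value and is not a call.

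PAX5 and EBF1 were expressed in MKL-1, MKL-2 and WaGa while most other early B genes stayed near 0, and EBF1 stood apart in MCC13 at 0.0126 TPM. RNA from B-lineage cells would bring the other early B genes along, but over 17 such genes the highest of the 3 median levels was 0.061% of the REH level, against 20.6% to 49.4% for PAX5. BLK in MKL-2 departed from this, at 40.0% of the REH level, as did IGHM, which is not among the 17 genes and stood at 342 TPM in MKL-1 and 535 TPM in MKL-2 against 236 TPM in REH. Reads of other PAX genes placed on PAX5 would lie in the paired-box exons, but the least covered of E5, E6, E7, E8 and E9, with E6/7 not counted, held 39.1% as many reads as E3. A difference between tumour types in how PAX5 and EBF1 are used may remain as a hypothesis, since it was found and tested on the same data and was not tested directly.

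MCC13 stood apart in more of the 20698 genes than any other Merkel cell carcinoma line. Its share of the values named in this part is not informative, because more genes were named for MCC13 than for each other line. TPM scaling between libraries is opposed by quantile normalization, after which 95.7% of the genes called for MCC13 were called again. A mixture of cells like the other 3 lines with another cell type would keep their abundant transcripts, but the median of 12 Merkel and neuroendocrine genes in MCC13 was 0.366% of the lowest of the other 3 lines (highest 9.65%, ENO2). A library of another line than its label says cannot be told apart from a true difference of the line, because the tables hold no value that identifies a line, and the highest Pearson correlation across genes of MCC13 with another line was 0.747, against 0.738 with REH. A biological difference of the line stays open and untested.

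PAX5 exon shares differed between the Merkel cell carcinoma lines and REH. Coverage falling along the transcript would move the ratios 1 way. Their mean at E3 and E4 and their mean at E7 and E8 exceeded that at E5 and E6 by at least 0.747 on the log2 scale. This argues against coverage alone for E3 to E8, but E1B and E10 were left out. With all exons counted, E1B, near the transcript start, fell from 17.5% in REH to 5.6%, 7.0% and 7.2% in MKL-1, MKL-2 and WaGa. E10, at its end, rose from 62.0% to 72.5%, 71.3% and 70.1%. E1A, the first exon, was not lower in MKL-1 or WaGa (0.295% and 0.222% against 0.165%). Coverage as a source of the E1B and E10 shifts stays open. Counting noise at E6/7 is opposed by Fisher's exact test, with a largest adjusted p of 1.05e-07. That test takes reads as independent and covers counting error only, so variation between libraries stays open. Unspliced PAX5 RNA over E6/7 cannot be told apart from a spliced exon, because intron reads were not analysed here, and at the E6/7 density it would give at most 8.34% of the E4 reads. Different transcript forms in the tumour types stay open and untested, and 1 REH library cannot separate the type from the line.

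Genes highest in MCC13 and standing apart there were VIM (3125 TPM), ANKRD1 (2320 TPM), CYR61 (1850 TPM), CCND1 (1484 TPM), TM4SF1 (1136 TPM), AKAP12 (1026 TPM), IGFBP7 (949 TPM), MMP1 (829 TPM), MSN (798 TPM), COL4A1 (793 TPM), GJA1 (788 TPM), COL4A2 (766 TPM) and AXL (579 TPM). Further such genes were COL5A1 (205 TPM), ARHGDIB (202 TPM), RAC2 (168 TPM), TNFRSF10B (125 TPM), ENG (118 TPM), DSC3 (61.7 TPM), DDX58 (46.6 TPM), NEDD9 (44.0 TPM), HLA-DPB1 (25.5 TPM), CD68 (17.3 TPM), IL7R (15.4 TPM), HLA-DPA1 (10.3 TPM), HLA-DMB (2.67 TPM) and CD8A (1.05 TPM), and, at levels near 0, APBB1IP (0.069 TPM) and RAG2 (0.0462 TPM).

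Genes lowest in MCC13 and standing apart there were MCM6 (82.7 TPM), NEFH (10.5 TPM), SNAP25 (5.74 TPM), RB1 (2.56 TPM), PAX6 (1.89 TPM), MAL2 (0.825 TPM), EPCAM (0.484 TPM), MTATP6P1 (0.296 TPM), CCER2 (0.241 TPM), POU4F3 (0.165 TPM), MYCL (0.148 TPM), HEPACAM2 (0.104 TPM), NEFM (0.0322 TPM), NEFL (0.0312 TPM), MAPT (0.0284 TPM), CPLX2 (0.0186 TPM) and KCNH6 (0.0102 TPM). ATOH1, INSM1, PCP4, SCNN1A, GNG8, ISL1, ESRP1 and RAB25 were listed at 0 in MCC13.

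In MKL-1, HAND2-AS1 (25.7 TPM), FGF7 (22.8 TPM) and MYO3A (16.8 TPM) stood above the other 3 lines, and SOX12 (0.83 TPM), MTAP (0.78 TPM), TES (0.015 TPM) and CDKN2A (listed at 0) below. In MKL-2, SOX2-OT (542 TPM), RORB (95.3 TPM), SLC6A19 (38.7 TPM), BLK (34.3 TPM) and ELF3 (23.7 TPM) stood above, and SNHG14 (0.0744 TPM), BLOC1S5-TXNDC5 and NSMAF (both listed at 0) below. In WaGa, GPX2 (278 TPM), KLRG2 (89.1 TPM), CTAG1B (47.4 TPM) and CTAG1A (47.3 TPM) stood above, as did IGLL1 (0.0601 TPM) and MPO (0.0393 TPM) near 0, and PEG10 and BIVM-ERCC5 (both listed at 0) below.

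List medians on the log2(TPM + 1) scale stood apart in MCC13 for the mesenchymal and adhesion (8.30), YAP and TAZ pathway (7.23), neuronal (0.95) and Merkel and neuroendocrine (0.448) lists. In MKL-2 they stood apart for the PAX family (1.34), myeloid (0.0779) and T and NK cell (0.0148) lists, the last of which lay near 0 in every line.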

How the results depend on the processing

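Of the results in this part, only Fisher's exact test of exon reads and the total without E10 and E1B were chosen after the data had been seen. Genes differing between the Merkel cell carcinoma lines and REH numbered 1166, 3794 without a filter (which adds genes near 0 in most lines), 288 at a mean of at least 5 TPM (fewer genes tested), and 0 to 2828 with 1 line left out, where 2828 was without MCC13 and 0 without MKL-1, MKL-2 or WaGa. The share of these genes that was higher was 20.8%, and 45.5% and 9.91% with pseudocounts of 0.1 and 5 TPM and 55.6% at a mean of at least 5 TPM. Genes differing in MCC13 numbered 1852, 3513 without a filter, 1167 at a mean of at least 5 TPM and 0 without MKL-1, MKL-2 or WaGa, and 72.4% were higher, against 58.0% with a pseudocount of 0.1 TPM and 46.5% at a mean of at least 5 TPM. For MKL-1, MKL-2 and WaGa, limma called 0 genes under every other setting and 1680, 1875 and 1410 without a filter. Without a filter, 99.5%, 99.4% and 100% of the genes called in MKL-1, MKL-2 and WaGa were higher in that single line. The genes that this setting adds lay below 1 TPM in every line compared. The cause was not tested beyond the construction of each setting.

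Gene lists passing numbered 11 against REH, 10 to 11 with 1 line left out and 1 with an estimated correlation. Between lines they numbered 24, 6 to 23 with 1 line left out (6 without MCC13) and 0 with an estimated correlation. Without MCC13, camera turned the direction of the Merkel and neuroendocrine list in MKL-1 (adjusted p = 0.172, and 2.83e-06 to 0.172 with 1 line left out). It also turned the YAP and TAZ pathway list in MKL-2 (adjusted p = 0.463, and 0.000631 to 0.463). The mesenchymal and adhesion list turned in WaGa (adjusted p = 0.176, and 1.06e-05 to 0.176). MCC13 was among the lines compared with in each case. The Merkel and neuroendocrine median (log2 scale) was 0.448 in MCC13, and the lowest in the other Merkel cell carcinoma lines was 7.02 in MKL-1. For YAP and TAZ it was 7.23 in MCC13, with MKL-2 highest of the others at 0.710. For mesenchymal and adhesion it was 8.30 in MCC13, with WaGa highest of the others at 1.03. These directions with MCC13 included thus followed the level of MCC13. Over all other list results 536 kept their side of the threshold, 19 newly passed and 62 no longer passed. For named genes these numbers were 3097, 48 and 350. The PAX5 difference from REH lay between -3.79 and -1.52 over its alternatives (limma, adjusted p from 0.211 to 0.707).

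The PAX5 exon profile distance from REH was 13.5 percentage points, 24.0 without E10, 15.8 without E10 and E1B, and 12.9 to 13.9 with 1 line left out. Pairs past Fisher's exact test numbered 31 of 36, 30 with reads divided by 2, 26 of 33 without E10, 27 of 30 without E10 and E1B, and 19 to 22 with 1 line left out (fewer pairs tested). No paired analysis was possible because the groups compared share fewer than 2 replicate numbers, and those were given in accession order. The depth behind TPM values was unknown, and 16 E6/7 reads in MKL-2 and 5 in REH limit that ratio.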

Other observations

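The tests of hypotheses in this part, and the genes named in it, were chosen after the values had been seen. Immunoglobulin heavy chain transcripts were present in MKL-1 and MKL-2. IGHM, the constant region of IgM, stood at 342 TPM in MKL-1 and 535 TPM in MKL-2, against 236 TPM in REH, 2.89 TPM in WaGa and a listed 0 in MCC13. All 9 annotated heavy chain J segments and pseudosegments reached 1 TPM in MKL-1 and in MKL-2, but only 1 in WaGa and 1 in REH (IGHJ6, 28.3 TPM). IGHD7-27, the D segment next to the J segments, stood at 16.5 TPM in MKL-1 and 53.1 TPM in MKL-2. These segments overlap and resemble one another, so single levels are uncertain. A hypothesis is that these were transcripts of an unrearranged heavy chain locus, for which no V segment should be joined. Of 130 V segments 0 reached 1 TPM in MKL-1 and MKL-2 together, as that hypothesis predicts, against 10 in REH. V segments that failed to be estimated in the TPM table could also give 0. Whether the 10 V segments of REH were joined was not tested. They therefore do not show that a joined V segment would be detected here.

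CD274, which encodes the checkpoint ligand PD-L1, stood at 22.2 TPM in MCC13 and between 0.0586 and 0.938 TPM in the other 4 lines. TERT, the catalytic subunit of telomerase, stood at 170 TPM in REH, 14.8 TPM in MKL-2, 3.04 TPM in MKL-1, 1.97 TPM in WaGa and 0.187 TPM in MCC13. PEG3, an imprinted gene, stood at 91.5 to 345 TPM in MKL-1, MKL-2 and WaGa and was listed at 0 in MCC13 and REH, as was its neighbour ZIM2.

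Neighbouring genes on chromosome 9 were near 0 together in REH. The run held 10 genes (SLC24A2, MLLT3, FOCAD, KLHL9, MTAP, CDKN2A, CDKN2B, DMRTA1, ELAVL2 and TUSC1), each under 0.1 TPM in REH and at 5 TPM or more in at least 2 of the other 4 lines. RRAGA, HAUS6 and DENND4C, which lie nearby, stood at 62.6, 41.1 and 22.6 TPM in REH. The hypothesis of loss or silencing of a whole segment predicts a run longer than in shuffled gene order. The longest run over 10000 shuffles held 7 genes (permutation p = 1e-04, the smallest these shuffles can give), which is consistent with the hypothesis, although DNA was not analysed here and loss cannot be separated from silencing. In REH 8 of the 10 genes were listed at exactly 0, which failed estimates in the TPM table could also give. Shuffling ignores families of genes that are regulated together, such as the HOXD genes, which with MTX2 formed a run of 8 in REH. In MKL-1, where CDKN2A and CDKN2B were listed at 0 and MTAP stood at 0.78 TPM, the longest run held 4 genes, as many as the longest in shuffled order (permutation p = 0.0011). That run, of ATHL1, IFITM2, IFITM1 and IFITM3 on chromosome 11, was mostly of 1 family, and WaGa had the same run. It did not hold CDKN2A, CDKN2B or MTAP, so the test did not bear on them. The other genes of the chromosome 9 run in REH stood at 5.555 TPM (SLC24A2) to 103 TPM (ELAVL2) in MKL-1. The whole of that segment was therefore not near 0 in MKL-1, and loss or silencing of a smaller segment was not tested.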
